A study of Homo sapiens with 12 samples.

How the data were processed

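Bulk RNA-seq libraries were analysed from alveolar type 2-like cells made from a human induced pluripotent stem cell line (iPSC), per the labels. The line, BU3 NGST CRISPRi, carries a doxycycline-inducible CRISPR interference system, in which a catalytically dead Cas9 fused to a repressor is steered by a guide RNA to the start of a gene and lowers its transcription. The letters NGST are, as background, the usual name of a reporter pair on this parent line, a green fluorescent protein at NKX2-1 and tdTomato at SFTPC. The guide in these libraries is directed at ADGRG6. Cells had been differentiated through endoderm and sorted lung progenitors, and were kept in a distal lung medium with the GSK3 inhibitor CHIR99021, keratinocyte growth factor, dexamethasone, a cyclic AMP analog and a phosphodiesterase inhibitor, per the labels' protocols. Cultures received doxycycline or none, and were then exposed to air or to 5% cigarette smoke for 8 hours. The 12 libraries form 4 groups of 3. The labels number the replicates 1 to 3 in each group and call them biological. Nothing in the labels says whether they came from separate differentiations, so the p-values measure the spread between these cultures. That spread was estimated per gene over all 4 groups together.

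The deposited table holds whole-number counts per gene, one column per library, which the authors made with featureCounts from the Subread package, per the submitters' processing notes. The same notes list edgeR, limma and the genome build GRCh38. The aligner, the annotation release, the tool versions and the strand setting of the counting are not given in the sources used here. RNA was isolated with a Qiagen RNeasy kit per the labels. The labels name the molecule as polyA RNA in one field and describe ribosomal reduction of total RNA in another, so the library preparation is uncertain. This matters for transcripts without a poly(A) tail, such as most histone mRNAs.

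The table has 33551 rows, of which 33538 are genes. The other 13 are 2 reporter sequences (EGFP and tdTomato) and 11 that carry the names of coronavirus genes, and the latter had 0 counts in all 12 libraries. These 13 rows took 0.019% to 0.0271% of the counts of a library and stayed out of library sizes and tests. Gene identifiers, positions and exon overlaps were taken from GENCODE release 29 on GRCh38. Of the gene rows, 33047 matched 1 gene of that annotation by symbol and 491 did not. Since the strand setting is unknown, genes of greatest change that share exonic sequence with an antisense or overlapping gene are named as such. Other reported genes may share sequence without a remark.

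Library totals ranged from 42.8 to 79.9 M counts, a ratio of 1.87. CPM, counts scaled to a library of 1e6, are relative to library size scaled by trimmed mean of M values (TMM), and a mean ± SD is over the 3 libraries of a group. No pair of replicates was a copy of another. Their counts differed by 12.9 to 193 times the sampling variance, and their correlation of log2 CPM across genes was 0.9635 to 0.9891. The pair of air libraries without doxycycline numbered 2 and 3 was the most distant.

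The main test was edgeR's quasi-likelihood test (robust) with TMM scaling and edgeR's filter on low counts, which left 20255 genes. All 12 libraries entered 1 fit with 4 group means, with 8 residual degrees of freedom, and 5 contrasts were taken from it. These were doxycycline against none in air and in smoke, smoke against air without and with doxycycline, and the interaction, which is the difference of both smoke responses. Adjusted p refers to this test with Benjamini-Hochberg adjustment over all genes of a contrast, unless camera is named, and a gene is called below 0.05. Log2 fold changes carry standard errors from the same fit. An exact permutation of 3 against 3 libraries cannot give a p below 0.10, which is why single genes rest on the model fitted across all genes.

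There were 30 gene lists for stress responses, growth, signalling, matrix, junctions, mitochondria and markers of alveolar and other cell types. Each was tested with limma's camera on voom values with a preset inter-gene correlation of 0.01 and adjustment over the lists of a contrast. The lists came from general knowledge, and all had at least 5 tested members. Counts adjusted over the list alone treat each list as its own family of tests. Genes near ADGRG6 were those whose annotated start lies within 1 Mb of its start. The lists, contrasts, filters and tests were fixed before the data were examined. So was the rule for named genes, which takes ADGRG6 and, among called genes with a mean of at least 5 CPM and no overlap between the libraries compared, the 12 with the greatest rise and the 12 with the greatest fall. The overlap condition was not used for the interaction. The rule also takes the 4 members of each list with the smallest p, and any alveolar type 2 marker. Genes outside it are said to be chosen after their values were seen, and 2 genes that the rule takes are not reported.

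Alternatives fixed in advance were other scalings (DESeq2's size factors, upper quartile, library size alone), no filter on low counts and a stricter one of 5 CPM in 3 libraries, a block for the replicate number, a test against a 1.5-fold change, fits on only the groups compared, limma voom, DESeq2, and each of the 12 libraries left out in turn. For lists, camera with an estimated correlation and fry were run. A voom fit with library weights, and lists and across-gene correlations without 1 library that stood apart, were added after seeing the data. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

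The calls were tested on simulated data drawn from the real means and library sizes, with 50 genes changed at each of 4 fold sizes. Each gene had 1 spread for all groups there. Real replicates of air without doxycycline lay further apart than those of the other groups. The rates below may thus not hold for contrasts with that group. At 2-fold, 62% of changed genes were recovered for doxycycline in air, 64% for doxycycline in smoke, 66% for smoke without doxycycline, 40% for smoke with doxycycline and 46% for the interaction. At 1.5-fold the percentages in the same order were 52, 34, 34, 18 and 12, and at 4-fold they were 90, 84, 76, 68 and 64. Between 4 and 11 unchanged genes were called per comparison, among 19879 to 19920 genes run. Each comparison had its own random draw of changed genes, so these percentages cannot rank the doxycycline and smoke comparisons by power. With 1 of 30 random lists of 20 genes shifted 1.5-fold, camera called that list and 0 others. Genes were simulated independently of each other there. The real lists had estimated correlations from -0.0869 for aryl hydrocarbon receptor targets to 0.973 for mitochondrially encoded mRNAs in air. The simulation thus cannot show how camera with the preset correlation behaves on correlated lists. Replicates differed by well over the sampling variance, so for abundant genes the spread between cultures, a biological coefficient of variation of 16.8%, set the precision rather than depth.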

Results

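Gene expression was measured by bulk RNA-seq in iPSC-derived alveolar type 2 cells, the surfactant-producing cells of the lung alveolus grown here from stem cells, to compare cells with and without CRISPR interference knockdown of ADGRG6 after air or cigarette smoke. ADGRG6, also known as GPR126, is an adhesion G protein-coupled receptor whose known ligands include basement membrane proteins. Each of the 4 groups had 3 libraries: air without doxycycline, air with doxycycline, smoke without doxycycline and smoke with doxycycline. All libraries carried the ADGRG6 guide, and cells with a control guide and doxycycline were not analysed here, so an effect of the drug or of the induced repressor is part of every doxycycline contrast. The totals of replicates 1, 2 and 3 were 58.57, 42.8 and 58.04 M counts in air without doxycycline, 55.77, 67.17 and 51.37 M in air with doxycycline, 43.19, 57.65 and 52.33 M in smoke without doxycycline, and 61.64, 59.49 and 79.86 M in smoke with doxycycline. The first principal components held 35.5%, 19.6% and 9.99% of the variance. Replicate 2 of air without doxycycline stood apart on component 3, at -71.95 against -3.81 to 22 for the other 11 libraries. On component 1 replicates 1, 2 and 3 of air without doxycycline lay at -12.94, 35.28 and -58.04. Air libraries with doxycycline lay at 42.51 to 49.48 there.

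ADGRG6 was lower with doxycycline in both exposures. The gene (ENSG00000112414.14) lies on chromosome 6 from 142301854 to 142446266 on the plus strand of GRCh38. In air its level was 101 ± 13.1 CPM without and 62.5 ± 6.29 CPM with doxycycline (SD, n = 3 per group), a log2 fold change of -0.70 with a standard error of 0.105 and an adjusted p of 0.00128. In smoke it was 131 ± 12.1 CPM without and 74.7 ± 5.46 CPM with doxycycline, a log2 fold change of -0.81 (adjusted p 0.000351). The level with doxycycline was thus 61.7% of that without in air and 57.1% in smoke, and the libraries of each pair of groups did not overlap. ADGRG6 also rose with smoke in cells without doxycycline, by 0.37 on the log2 scale (adjusted p 0.0323). With doxycycline the change was 0.26 (adjusted p 0.109), and the difference between both smoke responses was -0.11 (adjusted p 0.886). The rise with smoke lost its call under library-size scaling (adjusted p 0.0698) and upper quartile scaling (adjusted p 0.052). It was also lost without replicate 1 of air without doxycycline (adjusted p 0.134) and without replicates 2 (0.0888) and 3 (0.146) of smoke without doxycycline.

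**Figure D1:**
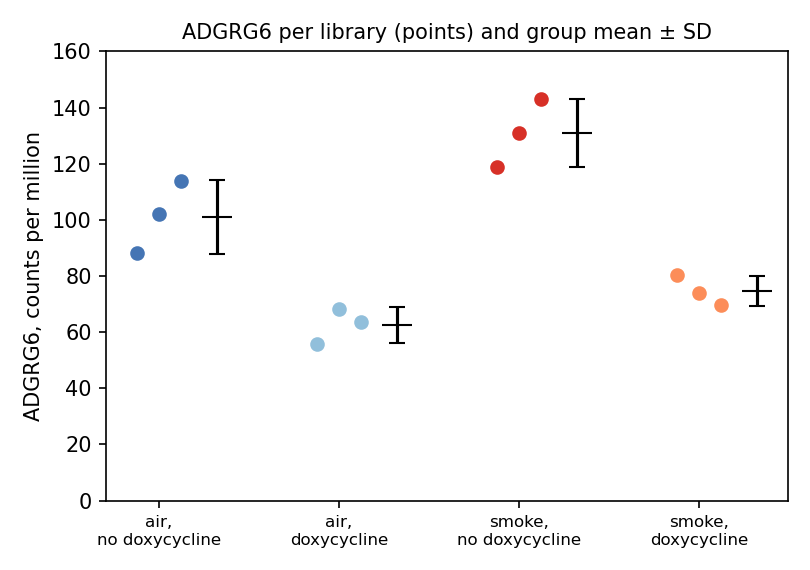
ADGRG6 in counts per M for each library (points, 3 per group) with the group mean ± SD beside them. Libraries with doxycycline lie between 55.8 and 80.5 CPM and those without between 88.1 and 143 CPM.

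The neighbours of ADGRG6 were examined because a repressor can act beyond its target. Of 15 genes whose start lies within 1 Mb of that of ADGRG6, 6 were expressed enough to test. VTA1, the nearest gene tested, at 154.7 kb, had log2 fold changes of 0.06 in air and 0.13 in smoke (adjusted p 0.75 and 0.289). AIG1, at 758.6 kb, had 0.28 in air (adjusted p 0.0534) and rose by 0.25 in smoke (adjusted p 0.0437). In air edgeR called 0 of the 6 genes, with 1 at an unadjusted p under 0.05, DESeq2 called 1 and limma voom 0. Adjusted over the list alone, AIG1 was the 1 gene called in air, and in smoke the count was 0, with 1 at the adjustment over all genes.

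In air, doxycycline was followed by more transcripts of cell division genes and of a small set of strongly induced genes, and by less of part of the transitional alveolar markers and of single genes for matrix proteins and matrix proteases. NPPC, which encodes the C-type natriuretic peptide precursor, rose 44.8-fold, from 0.523 ± 0.0984 to 23.9 ± 2.48 CPM (SD, n = 3 per group; log2 fold change 5.49, standard error 0.207, adjusted p 1.53e-09). NPPC lies on chromosome 2 from 231921820 to 231926403. Of the proliferation list 24 of 26 members rose, while MMP7, MMP1 and MMP2, secreted proteases of the matrix metalloproteinase family, fell by 3.13, 3.05 and 2.44 on the log2 scale (adjusted p 0.0312, 0.00608 and 0.00228). FN1, the gene of fibronectin, fell by 1.54 (adjusted p 5.5e-06) and COL3A1, a fibrillar collagen gene, by 2.42 (adjusted p 0.00107).

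Next to NPPC, the greatest rises in air among called genes with a mean of at least 5 CPM belonged to 3 neighbouring genes of chromosome 19. EPS8L1 (55072020 to 55087923, plus strand) rose by 3.15, PPP1R12C (55090913 to 55117559, minus strand) by 2.55 and RDH13 (55039108 to 55071291, minus strand) by 1.98 on the log2 scale, with adjusted p of 0.00152, 6.31e-08 and 5.62e-06. PPP1R12C went from 5.73 ± 0.85 to 33.5 ± 3.45 CPM. Intron sequence of PPP1R12C holds AAVS1, a site often used to insert transgenes; where the CRISPR interference cassette sits is not given in the sources used here. Further rises were those of NID2, a basement membrane nidogen, by 1.86, CLDN2, a tight junction claudin, by 1.60, PDE7B, a cyclic AMP phosphodiesterase, by 1.60, SLITRK5 by 1.45, PTPRZ1 by 1.42, ADAMTS3 by 1.38, GGT5 by 1.36 and RNASE1 by 1.35. Their adjusted p ran up to 0.0449, for PDE7B. Among the greatest falls were EEF1A2 (-3.56), a tissue-restricted elongation factor close in sequence to EEF1A1, SEMA5A (-2.97), INHBA (-2.96), an activin subunit, GREM1 (-2.71), a secreted BMP antagonist, UBASH3B (-2.63), IGFBP3 (-2.60), TM4SF1 (-2.54) and TUBB2B (-2.34), a tubulin that shares sequence with TUBB2A. EEF1A2 had the highest adjusted p among these apart from GREM1, 0.0238 against 0.0328. RDH13, NID2, CLDN2, PDE7B, ADAMTS3, SEMA5A, GREM1, TM4SF1 and TUBB2B share exonic sequence with a gene on the opposite strand.

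The proliferation genes were the most uniform group in air, with 24 of 26 members higher (26 adjusted over the list alone) and a median log2 fold change of 0.88. UBE2C, CDC20, RRM2 and PLK1 rose by 1.07, 1.02, 0.90 and 0.92 (camera adjusted p 8.13e-27; adjusted p = 0.353 with an estimated correlation). Of the 15 transitional alveolar epithelial markers, genes of a damage-associated state between type 2 and type 1 cells, 7 fell (13 adjusted over the list alone), among them KRT19 (-0.64), LGALS3 (-0.81) and KRT8 (-0.38), with a camera adjusted p of 7.61e-08 and an adjusted p = 0.353 with an estimated correlation. Of 20 p53 targets 6 fell (9 adjusted over the list alone), including TP53INP1 (-0.69), GADD45A (-0.88) and ZMAT3 (-0.42), with a camera adjusted p of 5.21e-05 and an adjusted p = 0.353 with an estimated correlation. In the list for TGF-beta and mesenchymal transition, 2 of 14 members fell (4 adjusted over the list alone), FN1 and TGFB2 (-0.46), at a camera adjusted p of 0.000159 and an adjusted p = 0.369 with an estimated correlation.

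Alveolar type 2 markers were higher in part. NAPSA, an aspartic protease of the lamellar body, rose by 0.86, CPM by 0.68, NKX2-1, the lung lineage transcription factor, by 0.38 and SFTA3 by 0.31, which makes 4 of 18 members (4 adjusted over the list alone; camera adjusted p 2.35e-05; adjusted p = 0.369 with an estimated correlation). The surfactant protein genes did not pass the test, with log2 fold changes of -1.08 for SFTPC (adjusted p 0.719), 0.64 for SFTPB and 1.52 for SFTPA1. Their levels in air without doxycycline were far apart. SFTPC was at 50.9, 1730 and 8.81 CPM in replicates 1, 2 and 3, against 285, 178 and 386 CPM with doxycycline, and SFTPB was at 959, 4300 and 474 CPM against 3480, 2730 and 2720 CPM. With replicate 2 of air without doxycycline left out, an alternative added after seeing the data, 8 of the 18 markers were higher (median log2 fold change 0.97, camera adjusted p 7.65e-11, with the preset correlation alone). The proliferation count was then 26 of 26 and 10 of the 15 transitional markers were lower. SFTPA1 and SFTPA2 are near-identical copies whose reads may have been split.

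**Figure D2:**
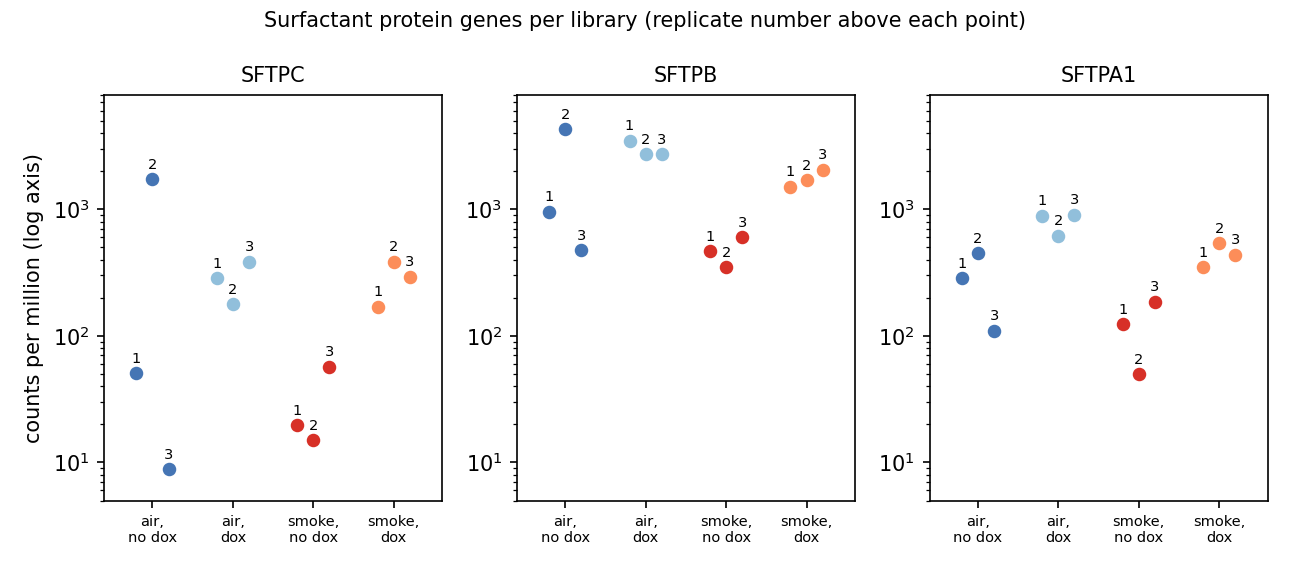
SFTPC, SFTPB and SFTPA1 in counts per M on a log axis, one point per library with its replicate number, by group. In air without doxycycline SFTPC runs from 8.81 CPM in replicate 3 to 1730 CPM in replicate 2, and the 3 libraries of every other group lie closer together.

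Matrix, signalling and mitochondrial lists were mixed in air. The basement membrane and laminin receptor genes, of which 4 fell and 2 rose among 27 (6 and 3 adjusted over the list alone), included LAMB1 (-1.87), ITGA6 (-0.93) and LAMA1 (-0.97), with a camera adjusted p of 0.0863 (adjusted p = 0.503 with an estimated correlation). Without replicate 2 of air without doxycycline 15 were lower and 2 higher (camera adjusted p 0.000899, with the preset correlation alone). Of the NRF2 antioxidant genes 4 fell and 1 rose among 24, the transporters ABCC2 (-2.28) and ABCC3 (1.05) most clearly (camera adjusted p 0.277), and of the hypoxia genes 3 fell, among them VEGFA (-0.68) and SLC2A1 (-1.24), and 1 rose among 17 (camera adjusted p 0.0605). In the cyclic AMP and CREB list 1 gene rose and 3 fell among 15 (7 and 3 adjusted over the list alone), AREG by -1.61, although the list ranked higher as a whole (camera adjusted p 0.0161; adjusted p = 0.353 with an estimated correlation). The NF-kB list had 3 of 18 lower and 1 higher, the YAP and TAZ list 3 of 16 lower and 1 higher, and the junction list 2 of 20 lower, with camera adjusted p of 0.0161, 0.019 and 0.0157 that became 0.369, 0.426 and 0.369 with an estimated correlation. The mitochondrially encoded mRNAs had a median of 0.38 and a camera adjusted p of 6.75e-05 (adjusted p = 0.402 with an estimated correlation), but edgeR, DESeq2 and limma voom called 0 of the 13, with 7 at an unadjusted p under 0.05. The nuclear-encoded respiratory chain had a median of 0.16 and a camera adjusted p of 0.000159 (adjusted p = 0.412 with an estimated correlation), with 0 of 26 called by any of the 3 tools and 4 at an unadjusted p under 0.05. In the list of histone mRNAs and small RNA host genes 1 of 9 rose (2 adjusted over the list alone), HIST1H2BK by 0.57 (camera adjusted p 0.0157; adjusted p = 0.412 with an estimated correlation).

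Markers of other cell types were also followed in air. KDR, an endothelial receptor, fell by 3.33 on the log2 scale (adjusted p 0.00229), as 1 of 6 endothelial and blood markers (camera adjusted p 0.0564). COL3A1 was the 1 of 7 mesenchymal markers that fell (camera adjusted p 0.0153; adjusted p = 0.353 with an estimated correlation), and COL1A1 had -1.37 (adjusted p 0.167). TTR (-1.93) and CDH17 (-2.36) fell among 8 non-lung endoderm markers, SALL4 (-1.25) fell among 6 pluripotency markers, and SPDEF (1.09) rose among 10 airway markers. Of 14 alveolar type 1 markers RTKN2 rose (0.46) and ANXA3 fell (-0.37).

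Stress and early response genes were mixed in air. Of 18 immediate early genes 4 rose, IER2 by 0.73 and JUN by 0.30, and 3 fell, FOSL1 by -1.58 and DUSP6 by -0.45 (0 and 3 with upper quartile scaling; camera adjusted p 0.263), and of 21 stress and unfolded protein response genes XBP1 (0.34) and PHGDH (0.64) rose and ATF3 (-1.01) fell (camera adjusted p 0.263). AHRR (-0.54) and TIPARP (-0.40) fell among 8 aryl hydrocarbon receptor targets, CELSR3 (-0.73) fell and ADGRL1 (0.49) rose among 18 adhesion receptors, and OAS1 (-1.21) fell among 16 interferon-stimulated genes, with camera adjusted p of 0.17, 0.127 and 0.905. With edgeR, 0 members were called for cholesterol synthesis, heat shock, metallothionein and neuroendocrine genes, with 1, 3, 1 and 2 at an unadjusted p under 0.05. DESeq2 called 1, 1, 0 and 1 of them and limma voom 0, 1, 0 and 0 (camera adjusted p 0.686, 0.523, 0.541 and 0.0602).

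In all, 1722 of 20255 genes were called in air with doxycycline against none, 830 higher and 892 lower, and 110 rose and 384 fell by over 2-fold. Of 30 lists 13 were called by camera with the preset correlation, 0 with an estimated one and 12 by fry. The count rose to 5009 without replicate 2 of air without doxycycline and dropped to 641, 764 and 1041 without replicates 1, 2 and 3 of air with doxycycline. It was 275 when only these 6 libraries were fitted, 93 against a 1.5-fold change and 5773 with voom library weights.

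In smoke, doxycycline was followed by more transcripts of cell division genes and of part of the alveolar type 2 markers. All 26 proliferation genes rose, NPPC rose 35.2-fold, from 0.427 ± 0.0524 to 15.2 ± 3.47 CPM (SD, n = 3 per group; log2 fold change 5.14, adjusted p 5.2e-09), and alveolar type 2 markers with LAMP3 and the surfactant genes SFTPA1 and SFTPA2 rose. Of the transitional markers 11 of 15 fell, of YAP and TAZ targets 13 of 16, of type 1 markers 8 of 14 and of the TGF-beta list 8 of 14, and 1 transitional marker and 2 YAP and TAZ targets rose. Each of these 4 lists had an adjusted p = 0.352 with an estimated correlation. FN1 fell by 1.43 on the log2 scale, and MMP7 fell 15-fold, from 50.9 ± 8.96 to 3.4 ± 0.975 CPM.

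Among the greatest rises after NPPC in smoke were AVPR1A (2.77), a vasopressin receptor, COL2A1 (2.73), DACT2 (2.63), EPS8L1 (2.50), LAMP3 (2.45), STUM (2.41), PPP1R12C (2.38), BMP3 (2.35), RGS16 (2.16), a regulator of G protein signalling, and PDE7B (2.12). Their adjusted p ran from 1.55e-07 for PPP1R12C to 0.0449 for COL2A1. RDH13, beside PPP1R12C, rose by 1.43 (adjusted p 9.14e-05). The greatest falls were SOX3 (-3.94), MMP7 (-3.90), SEMA5A (-3.68), EEF1A2 (-3.52), OLFML2A (-3.48), DLK1 (-3.47), HDAC9 (-3.44), IGFBP3 (-3.30), NRP2 (-3.26), a semaphorin and VEGF co-receptor, AHNAK2 (-3.16), CLIC5 (-3.14) and RAB3B (-3.10), with adjusted p of at most 0.0205, for DLK1. PDE7B, SEMA5A, NRP2 and AHNAK2 share exonic sequence with a gene on the opposite strand.

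**Figure D3:**
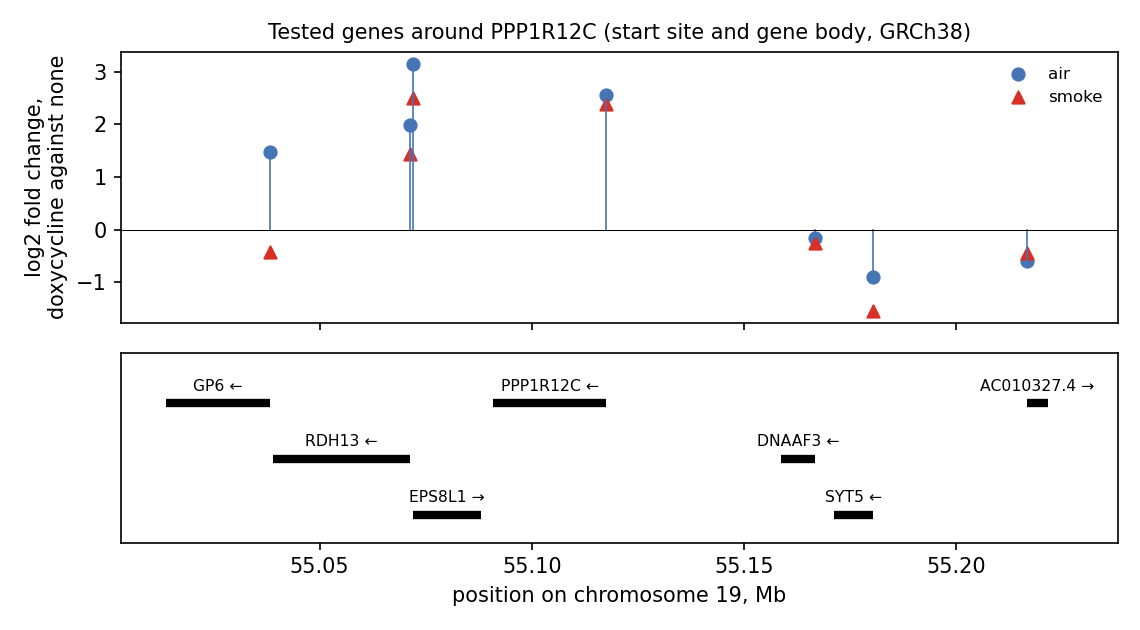
Log2 fold change with doxycycline of tested genes around PPP1R12C on chromosome 19, at their start sites, in air (blue circles) and smoke (red triangles), above the gene bodies with their strands. EPS8L1 (3.15 and 2.50), PPP1R12C (2.55 and 2.38) and RDH13 (1.98 and 1.43) rose in both.

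Proliferation genes had a median of 0.78 in smoke, with RRM2 at 0.96, TYMS at 0.87, UBE2C at 0.99 and MCM3 at 0.67 (26 of 26 higher, 26 adjusted over the list alone; camera adjusted p 3.14e-16; adjusted p = 0.352 with an estimated correlation). Of the transitional markers 11 of 15 fell and 1 rose (12 and 1 adjusted over the list alone), with KRT19 at -0.76, LGALS3 at -1.09, KRT7 at -0.97 and CLDN4 at -0.56 (camera adjusted p 9.76e-08; adjusted p = 0.352 with an estimated correlation). Of the YAP and TAZ targets 13 of 16 fell and 2 rose (13 and 2 adjusted over the list alone). AJUBA (-1.03), AMOTL2 (-1.37), CTGF (-1.46) and ANKRD1 (-2.58) led these, with a camera adjusted p of 2.46e-07 and an adjusted p = 0.352 with an estimated correlation. In the TGF-beta list 8 of 14 fell (10 adjusted over the list alone), with TGFB2 at -0.89, SKIL at -0.56 and SMAD7 at -0.68 (camera adjusted p 9.92e-07; adjusted p = 0.352 with an estimated correlation).

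Alveolar type 2 markers rose in 7 of 18 cases in smoke (10 adjusted over the list alone), with a median of 0.85 and a camera adjusted p of 1.25e-05 (adjusted p = 0.352 with an estimated correlation). NAPSA rose by 1.30, ABCA3, the lamellar body lipid transporter, by 0.96, LAMP3 by 2.45, SFTPA1 by 1.89, SFTPA2 by 1.71, CPM by 0.40 and SFTA3 by 0.34. SFTPB was 1.89 higher (adjusted p 0.0834) and SFTPC 3.21 higher (adjusted p 0.186) without passing the test; SFTPC was at 19.6, 14.9 and 56.9 CPM without and 170, 384 and 293 CPM with doxycycline. Of 14 type 1 markers 8 fell, with CLIC5 at -3.14, MYRF at -0.95, GPRC5A at -1.56 and CAV1 at -1.37 (8 lower and 1 higher adjusted over the list alone; camera adjusted p 0.00936; adjusted p = 0.352 with an estimated correlation). Among the 10 airway markers SOX2 (1.42), SPDEF (1.84) and TPPP3 (1.45) rose and TP63 (-1.43) fell (camera adjusted p 0.238).

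Part of the mitochondrial and stress genes rose in smoke. Of the nuclear-encoded respiratory chain 14 of 26 rose (21 adjusted over the list alone, 9 with upper quartile scaling), with ATP5F1B at 0.43, SDHB at 0.39 and COX5A at 0.36 (camera adjusted p 2.07e-07; adjusted p = 0.352 with an estimated correlation). MT-ND3 (0.54) rose as 1 of 13 mitochondrially encoded mRNAs (8 adjusted over the list alone, 0 with library-size or upper quartile scaling; camera adjusted p 0.00127; adjusted p = 0.482 with an estimated correlation). In the list for the integrated stress and unfolded protein responses 8 of 21 rose and 1 fell, with XBP1 at 0.70 and CALR at 0.38 (camera adjusted p 0.00178; adjusted p = 0.361 with an estimated correlation). MT2A (2.44), MT1E (3.20) and MT1X (0.79), metallothioneins of a family with similar sequences, rose among 5 members (camera adjusted p 0.0103; adjusted p = 0.352 with an estimated correlation). NRF2 targets had 9 of 24 higher (5 with library-size or upper quartile scaling) and 1 lower, heat shock genes 4 of 18 higher, cholesterol synthesis genes 2 of 20 and 1 lower, and histone and small RNA host genes 5 of 9. Their camera adjusted p were 0.0252, 0.0137, 0.00243 and 0.00117, and 0.507, 0.482, 0.492 and 0.352 with an estimated correlation.

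Matrix, junction and immune genes were lower in part in smoke. Of basement membrane genes 9 of 27 fell and 3 rose (13 and 3 adjusted over the list alone), with ITGA6 at -1.08 and LAMB1 at -1.24 against NID2 at 1.78 and LAMA3 at 1.46 (camera adjusted p 0.00117; adjusted p = 0.352 with an estimated correlation). Junction genes fell in 7 of 20 cases, with TJP1 at -0.32 and DSG2 at -0.59, p53 targets in 9 of 20 with 2 higher, with PHLDA3 at -0.79, and interferon-stimulated genes in 3 of 16, with OAS1 at -1.25. The camera adjusted p of these lists were 0.0092, 0.0025 and 0.0252, and 0.352, 0.352 and 0.507 with an estimated correlation. Among 18 other adhesion receptors of the ADGRG6 family 5 fell and 3 rose, with CELSR3 at -0.82, ADGRF4 at -2.97 and ADGRL1 at 0.75 (camera adjusted p 0.0278; adjusted p = 0.352 with an estimated correlation). Of the markers of other cell types COL3A1 (-2.05) and COL1A1 (-2.04) fell among 7 mesenchymal genes (camera adjusted p 0.0183; adjusted p = 0.352 with an estimated correlation), and KDR (-3.41) and VWF (-1.09) fell among 6 endothelial and blood genes (camera adjusted p 0.0341; adjusted p = 0.352 with an estimated correlation). CDH17 (-3.24) and TTR (-1.35) fell and FGA (2.78) rose among 8 non-lung endoderm genes (camera adjusted p 0.967).

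Signalling lists without a camera call in smoke still had called members. SIK1 (-1.47) fell while PDE4D (1.01), RGS2 (0.94), PPARGC1A (1.37) and 2 others of 15 cyclic AMP and CREB targets rose (camera adjusted p 0.191). JUNB (0.73), IER2 (0.66) and FOS (1.49) rose among 18 immediate early genes (1 with upper quartile scaling; camera adjusted p 0.382). IL1A (-1.25) and NFKB2 (-0.54) were 2 of 3 falling NF-kB genes of 18, and CXCL2 (0.70) and SOD2 (0.48) rose (camera adjusted p 0.216). SLC2A1 (-1.28), PFKFB3 (-0.61) and ADM (-1.18) fell and LDHA (0.68) rose with 1 other among 17 hypoxia genes (1 higher and 5 lower with upper quartile scaling; camera adjusted p 0.386). AHRR (0.77) rose among 8 aryl hydrocarbon receptor targets (camera adjusted p 0.23). CHGB (-1.77) fell and 1 other member rose among 9 neuroendocrine markers (camera adjusted p 0.265), and SALL4 (-0.91) fell among 6 pluripotency markers (camera adjusted p 0.576).

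The test called 4748 genes for doxycycline in smoke, 2599 higher and 2149 lower, and 310 rose and 936 fell by over 2-fold. The split was 2013 higher and 2519 lower with library-size scaling and 1819 and 2691 with upper quartile scaling. The count was 2136 and 2667 without replicates 1 and 3 of smoke without doxycycline, 2760, 2628 and 2527 without replicates 1, 2 and 3 of smoke with doxycycline, 7161 with these 6 libraries alone, 7339 with voom library weights and 280 against a 1.5-fold change.

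The doxycycline responses in air and in smoke, which share no library, had a Pearson r of 0.63 (Spearman 0.597) across the 20255 tested genes, and 0.796 among 11461 genes with a mean of at least 5 CPM. Genes are not independent replicates, so no p is given. NPPC, EPS8L1, PPP1R12C, RDH13 and PDE7B were among 632 genes that rose in both, where independent lists of these sizes would share 107, and 599 fell in both against 94.6. Opposite calls were made for 14 genes.

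Smoke in cells without doxycycline raised 6 of 8 aryl hydrocarbon receptor targets and 14 of 24 NRF2 antioxidant genes, and lowered 1 of the latter. HMOX1, heme oxygenase 1, rose 109-fold, from 6.32 ± 3.25 to 678 ± 82 CPM (SD, n = 3 per group; log2 fold change 6.76, adjusted p 0.000307). CYP1A1 and CYP1B1, cytochrome P450 enzymes induced through the aryl hydrocarbon receptor, rose from 24.9 ± 20.2 to 692 ± 20 CPM (log2 fold change 4.80, adjusted p 0.00172) and from 58.1 ± 16.3 to 1310 ± 77.5 CPM (4.50, adjusted p 2.16e-07). AHRR, the repressor of that receptor, rose by 2.88 (adjusted p 1.18e-08), and SLC7A11, the cystine transporter that feeds glutathione synthesis, by 3.13. AVPR1A, PRR15L, BMP3 and FGF20 were among the greatest falls.

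Further rises without doxycycline were EID3 (2.52), STC2 (2.49), GCLM (2.38), a subunit of the rate-limiting glutathione synthesis enzyme, MMP1 (2.29), GREM1 (2.24) and FOXQ1 (2.21). CYP1B1-AS1 (2.58) lies opposite CYP1B1 and shares sequence with it. With the strand setting unknown, part of its reads may stem from CYP1B1. CYP1B1 also shares exonic sequence with RMDN2 on the opposite strand and RMDN2-AS1 on the same strand. HHIP, named below, shares it with HHIP-AS1 on the opposite strand, and AHRR overlaps PDCD6 on the same strand. Among the greatest falls were AVPR1A (-3.07), PRR15L (-2.80), PDE7B (-2.48), RGS7BP (-2.38), BMP3 (-2.38), FGF20 (-2.33), C9orf152 (-2.32), TFAP2B (-2.06), HHIP (-2), PPP1R3C (-2) and TNFSF15 (-1.90). Their adjusted p ran from 1.41e-05 for FGF20 to 0.0453 for HHIP. Many of these genes were spread in air without doxycycline: HHIP was at 15.9 ± 15.2 CPM and PRR15L at 14.9 ± 10.9 CPM there.

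Of the NRF2 targets 14 of 24 rose and 1 fell (17 and 1 adjusted over the list alone), with TXNRD1 at 1.55, GCLC at 1.67 and GCLM at 2.38 (camera adjusted p 1.32e-15; adjusted p = 0.154 with an estimated correlation). Of 8 aryl hydrocarbon receptor targets 6 rose (6 adjusted over the list alone), with TIPARP at 1.87 and NFE2L2 at 0.75, and this list kept its call with an estimated correlation (camera adjusted p 2.85e-10; adjusted p = 0.00356 with an estimated correlation). Heat shock genes rose in 7 of 18 cases, with BAG3 at 0.75, DNAJA1 at 0.68 and DNAJB1 at 0.78, and immediate early genes in 5 of 18 with 1 lower, with ATF3 at 1.68, FOSL1 at 2.15, MYC at 1.29 and JUN at -0.41. Their camera adjusted p were 1.48e-05 and 0.000315, and 0.367 and 0.351 with an estimated correlation. In the hypoxia list 6 of 17 rose and 1 fell, SLC2A1 by 1.63 and ALDOA by -1.20 (camera adjusted p 0.00118; adjusted p = 0.0734 with an estimated correlation). DNAJB9 (1.10) and HSPA5 (0.35), chaperones of the endoplasmic reticulum, were among 5 of 21 stress and unfolded protein response genes that rose (2 with library-size scaling; camera adjusted p 0.00812; adjusted p = 0.696 with an estimated correlation).

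Epithelial state genes moved as well without doxycycline. Transitional markers rose in 8 of 15 cases (8 adjusted over the list alone), with GDF15 at 1.18, LGALS3 at 0.84, HBEGF at 1.58 and CLDN4 at 0.45 (camera adjusted p 6.04e-09; adjusted p = 0.274 with an estimated correlation). Junction genes rose in 8 of 20 cases and fell in 1 (10 and 1 adjusted over the list alone), with TJP1 at 0.60, CTNNA1 at 0.55 and OCLN at 0.52, and YAP and TAZ targets rose in 6 of 16 (7 higher and 1 lower adjusted over the list alone), with LATS2 at 0.89, TEAD1 at 0.55 and AJUBA at 0.72. Their camera adjusted p were 1.48e-05 and 0.00018, and 0.154 and 0.367 with an estimated correlation. Among alveolar type 2 markers ETV5 (-0.71), CPM (-0.50) and NAPSA (-0.52) fell, 3 of 18, with a median of -0.88 (camera adjusted p 5.78e-05; adjusted p = 0.55 with an estimated correlation). Replicate 2 of the air group had the highest SFTPC, and without it 3 markers were lower, the median was -0.31 and the camera adjusted p 0.0104, with the preset correlation alone. Airway markers FOXJ1 (-1.42), SOX2 (-1.11) and SPDEF (-1.30) fell, 3 of 10 (5 adjusted over the list alone; camera adjusted p 0.00243; adjusted p = 0.081 with an estimated correlation).

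Other lists were mixed or had few called members with smoke without doxycycline. Proliferation genes had a median of -0.23 and a camera adjusted p of 0.03 (adjusted p = 0.945 with an estimated correlation), with 0 of 26 called by edgeR and limma voom (3 lower by edgeR with library-size scaling), 1 by DESeq2 and 6 at an unadjusted p under 0.05. In the NF-kB list the chemokine genes CXCL2 (-1.18) and CXCL3 (-1.75) fell and LIF (1.64) rose (camera adjusted p 0.88). Among the cyclic AMP and CREB targets 5 of 15 rose, NR4A3 by 1.58, and 5 fell, PDE4B by -1.42 (camera adjusted p 0.924). SC5D (0.78) rose as 1 of 20 cholesterol synthesis genes, TGFB2 (-0.81) fell as 1 of 14 genes of the TGF-beta list, and among p53 targets GDF15 and CDKN1A (0.62) rose while SESN1 (-0.96) and XPC (-0.38) fell. Camera adjusted p for these lists were 0.184, 0.184 and 0.564. The cholesterol result hung on replicate 2 of air without doxycycline. With that library left out, 11 of the 20 cholesterol synthesis genes rose (median 0.34, camera adjusted p 2.26e-09, with the preset correlation alone). Of 18 adhesion receptors 5 fell, CELSR2 by -0.46 and ADGRB3 by -1.02, and 1 rose, and AGER (-0.65) and RTKN2 (-0.44) fell among 14 alveolar type 1 markers (camera adjusted p 0.88 and 0.376). H1F0 (-0.69) and LIN28B (-0.48) were the 1 falling member each of the histone and pluripotency lists, and LIN28B was not called with the size factors of DESeq2 (camera adjusted p 0.754 and 0.0759).

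For 8 other lists edgeR called 0 members with smoke without doxycycline. Basement membrane, interferon-stimulated, non-lung endoderm and respiratory chain genes had 4, 4, 2 and 4 members at an unadjusted p under 0.05, of which DESeq2 called 2, 1, 1 and 0 and limma voom 1, 0, 0 and 0 (camera adjusted p 0.754, 0.2, 0.518 and 0.796). Endothelial, mesenchymal and metallothionein genes had 0 at an unadjusted p under 0.05 and 0 with DESeq2 or limma voom (camera adjusted p 0.754, 0.363 and 0.907). The same held for the mitochondrially encoded mRNAs (camera adjusted p 0.578).

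Smoke without doxycycline gave 2517 called genes, 1319 higher and 1198 lower, of which 201 and 331 changed by over 2-fold. Library-size and upper quartile scaling gave splits of 908 against 1792 and 1085 against 1513. The count was 1403 and 4478 without replicates 1 and 3 of air without doxycycline, 1454 and 1212 without replicates 2 and 3 of smoke without doxycycline, 816 with these 6 libraries alone, 118 against a 1.5-fold change and 6463 with voom library weights.

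With doxycycline, smoke raised 5 of 8 aryl hydrocarbon receptor targets, 21 of 24 NRF2 antioxidant genes and part of the heat shock, unfolded protein response and cholesterol synthesis genes, and lowered 1 NRF2 gene. HMOX1 rose 182-fold, from 4.57 ± 1.4 to 830 ± 476 CPM (SD, n = 3 per group; log2 fold change 7.51, adjusted p 8.91e-05), CYP1A1 from 12.2 ± 4.4 to 1390 ± 111 CPM (6.83, adjusted p 0.000267) and CYP1B1 from 70.7 ± 12.1 to 1680 ± 69.2 CPM (4.57, adjusted p 1.37e-07). AHRR rose by 4.19 (adjusted p 2.27e-10) and FOXQ1, a forkhead transcription factor, by 4.27. The greatest falls were PRR15L (-2.57), TRIL (-2.19) and PDE4B (-2.12).

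Further rises with doxycycline were GREM1 (4.14), MMP1 (4.09), SLC7A11 (3.95), PLAU (3.41), the urokinase gene, CYP1B1-AS1 (3.12), CCDC141 (3.04), which overlaps TTN on the same strand, and AREG (2.85), an EGF receptor ligand. MMP1 and GREM1 started from 0.299 ± 0.148 and 0.65 ± 0.064 CPM, near the low end of what was measured. Further falls were PDE7B (-1.96), MYCN (-1.90), FGF18 (-1.82), TNFSF15 (-1.72), BAMBI (-1.72), SHH (-1.71), TGFBR3 (-1.68), CHST2 (-1.65) and TRPC6 (-1.65), with adjusted p of at most 0.0112, for PDE7B. SHH and FGF18 are signals of lung branching, and TRPC6, a cation channel, went from 322 ± 59.8 to 103 ± 19.3 CPM. MYCN overlaps an antisense gene, as do TRIL, PDE7B, GREM1 and PLAU.

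NRF2 targets rose in 21 of 24 cases and fell in 1 (22 and 1 adjusted over the list alone), with a median of 1.03, TXNRD1 at 1.86, GCLC at 2.06 and NQO1 at 2.17 (camera adjusted p 3.43e-19; adjusted p = 0.0966 with an estimated correlation). Of 8 aryl hydrocarbon receptor targets 5 rose (5 adjusted over the list alone), TIPARP by 2.34 (camera adjusted p 2.07e-09; adjusted p = 0.00486 with an estimated correlation), and of 17 hypoxia genes 9 rose (10 adjusted over the list alone), VEGFA by 0.72, SLC2A1 by 1.58 and PGK1 by 0.33 (camera adjusted p 0.000144; adjusted p = 0.0298 with an estimated correlation). These 2 lists kept their call with an estimated correlation. Heat shock genes rose in 13 of 18 cases (16 adjusted over the list alone), with BAG3 at 0.99 and HSPH1 at 1.35, and stress and unfolded protein response genes in 13 of 21 (16 adjusted over the list alone, 6 with library-size scaling), with ATF3 at 2.43, HSPA5 at 0.59 and XBP1 at 0.55. Their camera adjusted p were 3.31e-08 and 1.35e-06, and 0.28 for both with an estimated correlation. Cholesterol synthesis genes rose in 8 of 20 cases (12 adjusted over the list alone), with NSDHL at 0.62, MSMO1 at 0.92 and SC5D at 0.53 (camera adjusted p 8.45e-06; adjusted p = 0.624 with an estimated correlation).

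Among the epithelial groups with doxycycline, GDF15 (2.34), AREG and HBEGF (1.31) rose with 2 other transitional markers of 15 (3 higher and 1 lower with library-size or upper quartile scaling; 7 higher and 1 lower adjusted over the list alone; camera adjusted p 0.000912; adjusted p = 0.624 with an estimated correlation). Junction genes rose in 6 of 20 cases and fell in 1, with DSP at 0.65, CTNNA1 at 0.60 and CLDN7 at 0.32 (3 higher with library-size scaling; camera adjusted p 0.000642; adjusted p = 0.28 with an estimated correlation). CPM (-0.78) and ETV5 (-0.52) fell among 18 alveolar type 2 markers (camera adjusted p 0.00868; adjusted p = 0.76 with an estimated correlation), while SFTPB had -0.76 (adjusted p 0.507). FOXJ1 (-1.30) and TP63 (-1.24) fell among 10 airway markers (camera adjusted p 0.00217; adjusted p = 0.0773 with an estimated correlation). PLK1 (-0.55) fell as 1 of 26 proliferation genes (7 with library-size and 6 with upper quartile scaling; camera adjusted p 0.000934; adjusted p = 0.76 with an estimated correlation), immediate early genes rose in 7 of 18 cases, MYC by 2.00 and FOSL1 by 2.80, with JUN (-0.50) lower (camera adjusted p 0.00524; adjusted p = 0.576 with an estimated correlation), and COX4I1 (0.32), COX5A (0.31) and COX6C (0.30) rose among 26 respiratory chain genes (1 with library-size scaling; camera adjusted p 0.0043; adjusted p = 0.76 with an estimated correlation). MT1E (2.09) and MT2A (1.29) rose among 5 metallothionein and zinc export genes (camera adjusted p 0.00868; adjusted p = 0.28 with an estimated correlation).

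Signalling, matrix and immune lists moved in both directions with smoke under doxycycline. LIF (2.48), NFKBIA (0.79), ICAM1 (0.99) and 1 other NF-kB gene of 18 rose and CXCL3 (-0.96) fell (3 higher and 3 lower with library-size scaling). PDE4B was 1 of 2 falling cyclic AMP and CREB targets of 15, and NR4A3 (1.70), CREM (0.78) and 2 others rose (4 higher and 4 lower with library-size or upper quartile scaling). Of 20 p53 targets 4 rose, GDF15 and AEN (0.58) among them, and 4 fell, DDB2 by -0.66 and MDM2 by -0.31. FN1 (0.42) and SNAI1 (1.02) rose and TGFB2 (-1.24) and SMAD7 (-0.54) fell in the TGF-beta list of 14 (0 higher and 3 lower with library-size or upper quartile scaling), and 2 of 16 YAP and TAZ targets rose, F3 by 0.53, and 4 fell, AMOTL2 by -0.61 (1 and 5 with library-size scaling). The camera adjusted p of these lists in the same order were 0.657, 0.626, 0.754, 0.642 and 0.521. LAMB1 (0.92) rose and HSPG2 (-0.52), COL4A3 (-1.06) and COL4A4 (-0.62) fell among 27 basement membrane genes (5 lower with library-size scaling; camera adjusted p 0.253). ADGRF1 (3.17) rose and ADGRB3 (-0.94) and CELSR2 (-0.35) fell among 18 adhesion receptors (5 lower with library-size scaling; camera adjusted p 0.476).

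Single members passed in other lists under doxycycline: RTKN2 (-0.58) of the type 1 markers, SNHG15 (0.88) of the small RNA host genes, IFI44L (-0.85) of the interferon-stimulated genes and DNMT3B (-0.74) of the pluripotency markers, with camera adjusted p of 0.193, 0.482, 0.476 and 0.437. Among neuroendocrine markers CALCA (0.71) rose and INSM1 (-1.81) fell (camera adjusted p 0.684). With edgeR 0 endothelial, mesenchymal, mitochondrially encoded and non-lung endoderm genes were called, with 0, 1, 0 and 1 at an unadjusted p under 0.05. DESeq2 called 1 mesenchymal gene and 0 of the rest, and limma voom 0 of each (camera adjusted p 0.904, 0.476, 0.542 and 0.681).

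For smoke with doxycycline 3556 genes were called, 2124 higher and 1432 lower, of which 320 and 350 changed by over 2-fold. Library-size scaling, which shifted the median of all genes by -0.117 on the log2 scale, gave 1213 higher and 2617 lower, and upper quartile scaling 1595 and 1935. The count was 2025 and 2125 without replicates 1 and 3 of air with doxycycline, 1834 without replicate 1 of smoke with doxycycline, 6226 with these 6 libraries alone, 6004 with voom library weights and 243 against a 1.5-fold change.

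**Figure D4:**
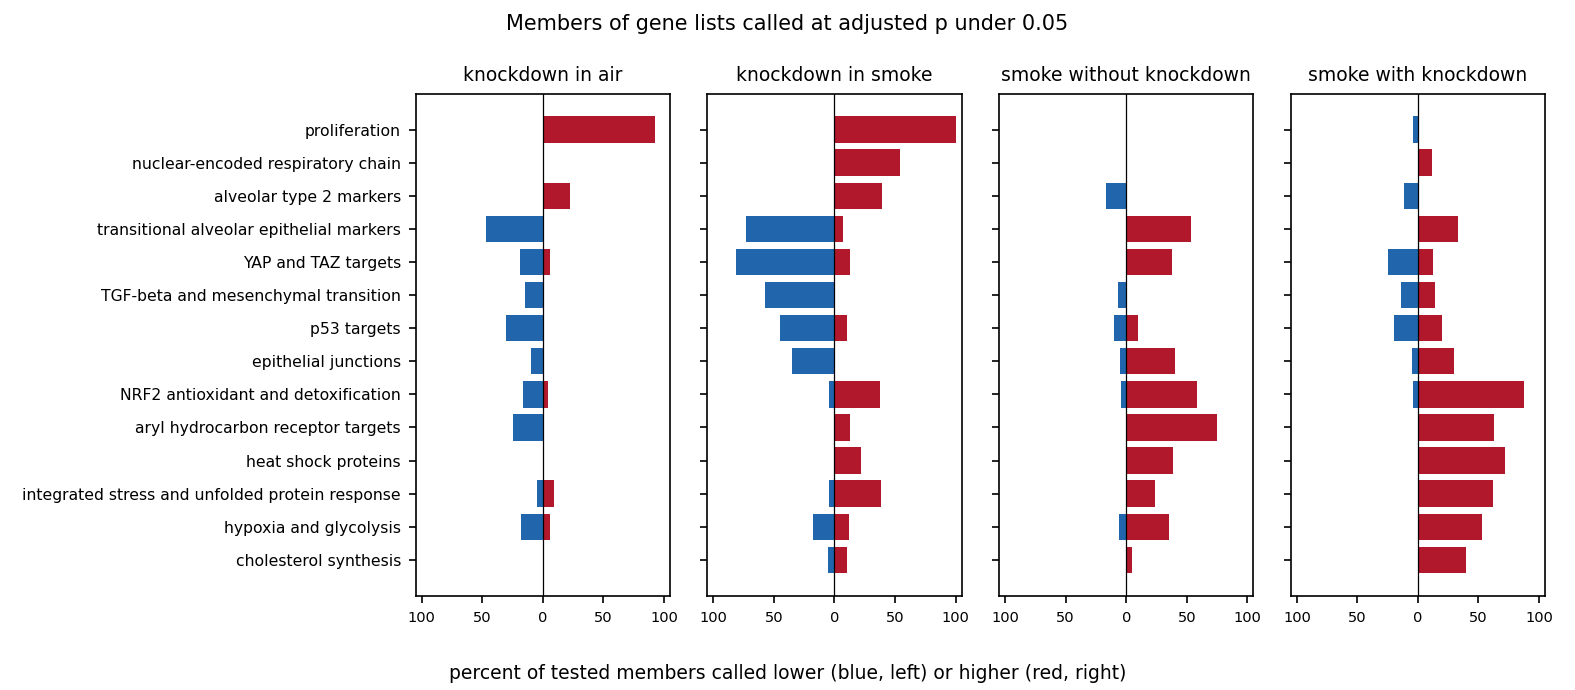
Percent of tested members of 14 gene lists called higher (red, right) or lower (blue, left) at an adjusted p under 0.05 in 4 comparisons; knockdown means doxycycline against none, and smoke means smoke against air. Proliferation genes are called with doxycycline in 24 and 26 of 26 cases, and NRF2 targets with smoke in 14 and 21 of 24 cases as higher.

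Both smoke responses, which share no library, had a Pearson r of 0.507 (Spearman 0.516) across 20255 tested genes and 0.747 among 11461 genes with a mean of at least 5 CPM. HMOX1, CYP1A1, CYP1B1, SLC7A11, AHRR, MMP1, GREM1 and FOXQ1 were among 982 genes that rose in both, where independent lists of these sizes would share 138, and PRR15L, PDE7B and TNFSF15 among 625 that fell in both, against 84.7. Opposite calls were made for 3 genes.

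**Figure D5:**
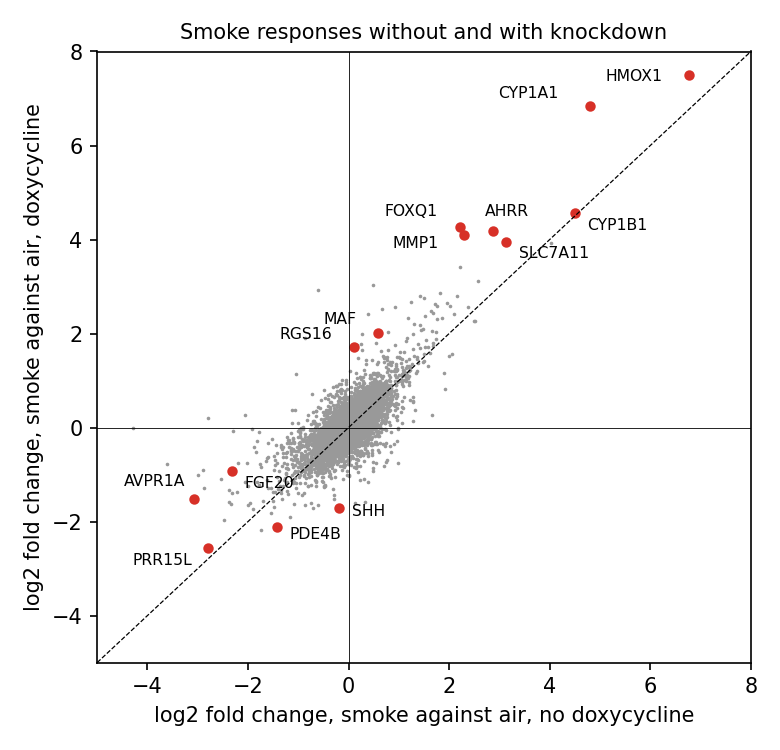
Log2 fold change of smoke against air without doxycycline (horizontal) and with doxycycline (vertical) for genes whose average log2 CPM from edgeR is at least the log2 of 5. Selected genes are in red, and the dashed line is equal change. The Pearson r of 0.747 is over the 11461 genes with a mean of at least 5 CPM, a set that may differ from the plotted one. FOXQ1, at 2.21 and 4.27, lies above the line.

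Whether the smoke response differed between cells without and with doxycycline was tested with the interaction, which called 18 genes, 15 with a positive and 3 with a negative difference. FOXQ1 went from 9.11 ± 2.59 to 42.2 ± 1.38 CPM with smoke without doxycycline and from 3.64 ± 0.952 to 70.5 ± 4.48 CPM with it (SD, n = 3 per group), a log2 difference of 2.07 with a standard error of 0.267 and an adjusted p of 0.0293. AHRR had a difference of 1.31 (adjusted p 0.0284), from 4.38 ± 0.478 to 32.2 ± 2.39 CPM without and from 3.03 ± 0.444 to 55 ± 6.77 CPM with doxycycline, and MAF, a bZIP transcription factor, one of 1.44 (adjusted p 0.0284). RGS16 was at 9.54 ± 2.44 and 10.3 ± 1.7 CPM in air and smoke without doxycycline and at 14.1 ± 2.33 and 46.1 ± 4.74 CPM with it, a difference of 1.59. TNFRSF11B, the gene of osteoprotegerin, had 2.04, C2CD4A 1.65, FLRT3 1.44, FAM89A 1.25, PLPP3 1.09, BCL2L11, a proapoptotic gene, 1.00 and TCIM 0.98, each with an adjusted p of 0.0338. TMEM200C had 0.83 (adjusted p 0.0426). RBMS3 (-0.78, adjusted p 0.0303), ST3GAL5 (-0.76, adjusted p 0.0426) and E2F7 (-0.73, adjusted p 0.0338) had negative differences. RBMS3 went from 22.9 to 20.9 CPM without and from 28.6 to 15.3 CPM with doxycycline, and E2F7 from 18.6 to 68.9 and from 27.5 to 61.5 CPM. AHRR, PLPP3 and RBMS3 share sequence with another gene on the same strand, and BCL2L11 and TMEM200C with one on the opposite strand.

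At the level of lists, camera with the preset correlation called 12 of 30 for the interaction, 0 with an estimated correlation and 1 by fry, the aryl hydrocarbon receptor targets (fry adjusted p 0.00638). These 8 targets had a median difference of 0.31 and 1 called member, AHRR (2 adjusted over the list alone; camera adjusted p 0.00517; adjusted p = 0.338 with an estimated correlation). The YAP and TAZ targets ranked lower, with a median of -0.37, CTGF at -1.47 (adjusted p 0.176) and AJUBA at -0.75 (adjusted p 0.238). Of these 16 genes edgeR and limma voom called 0, DESeq2 3, and 7 had an unadjusted p under 0.05 (6 lower adjusted over the list alone; camera adjusted p 5.75e-08; adjusted p = 0.35 with an estimated correlation). For NRF2 targets the median was 0.32 and 0 of 24 were called by edgeR, DESeq2 or limma voom, with 6 at an unadjusted p under 0.05 (camera adjusted p 1e-05; adjusted p = 0.55 with an estimated correlation). Cholesterol synthesis had a median of 0.40 with 0 of 20 called by the 3 tools and 4 at an unadjusted p under 0.05 (camera adjusted p 4.09e-05; adjusted p = 0.676 with an estimated correlation). Metallothionein, heat shock, respiratory chain and stress and unfolded protein response genes ranked higher and type 1, interferon-stimulated, TGF-beta and basement membrane genes lower. Each had 0 members called by the 3 tools, and their counts at an unadjusted p under 0.05 were 2, 1, 0, 4, 1, 1, 4 and 3. The remaining 18 lists had camera adjusted p from 0.0715 for histone and small RNA host genes to 0.952 for mesenchymal markers and 0 members called by edgeR. Among them proliferation genes (0.214) had 0 and alveolar type 2 markers (0.214) 1 at an unadjusted p under 0.05, with 0 by DESeq2 and limma voom. DESeq2 called 2 p53 targets, 1 NF-kB gene and 1 transitional marker, and limma voom 0 of each. Without replicate 2 of air without doxycycline, proliferation genes were among the lists that gained a camera call (adjusted p 0.00107, with the preset correlation alone). Heat shock, respiratory chain and basement membrane genes then lost theirs (0.192, 0.332 and 0.31), and cholesterol synthesis had 0.0411.

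The interaction count of 18, against 1550 genes at an unadjusted p under 0.05, moved with nearly every library left out. It was 4, 78 and 660 without replicates 1, 2 and 3 of air without doxycycline, 2, 0 and 4 without those of air with doxycycline, 0, 1 and 0 without those of smoke without doxycycline, and 0 and 1 without replicates 2 and 3 of smoke with doxycycline. It was 9 higher and 4 lower with library-size scaling, 5 with the 5 CPM filter, 0 against a 1.5-fold change, 3 with limma voom, 715 with voom library weights and 101 with DESeq2.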

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

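The interaction was fixed as a test in advance, while the weighing of the neighbourhood of PPP1R12C, of the air library that stood apart and of cell state was chosen after the results were seen, except for the depth test and the relabelling of libraries.

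The smoke response differed with doxycycline for 18 genes. Among those named, the differences on the log2 scale were FOXQ1 2.07, TNFRSF11B 2.04, C2CD4A 1.65, RGS16 1.59, FLRT3 1.44, MAF 1.44, AHRR 1.31, FAM89A 1.25, PLPP3 1.09, BCL2L11 1, TCIM 0.98, TMEM200C 0.83, RBMS3 -0.78, ST3GAL5 -0.76 and E2F7 -0.73. Lists with a camera call for this difference and a higher rank were NRF2 targets (adjusted p 1e-05), cholesterol synthesis (4.09e-05), stress and unfolded protein response (0.00123), respiratory chain (0.00425), metallothioneins (0.0049), aryl hydrocarbon receptor targets (0.00517) and heat shock genes (0.0085). Those with a lower rank were YAP and TAZ targets (5.75e-08), interferon-stimulated genes (0.0049), type 1 markers (0.00517), the TGF-beta list (0.0053) and basement membrane genes (0.0222). With an estimated correlation 0 lists were called, with NRF2 targets at 0.55 and cholesterol synthesis at 0.676, and fry called 1, the aryl hydrocarbon receptor targets. Without replicate 2 of air without doxycycline, camera with the preset correlation called 13 lists. Respiratory chain, heat shock and basement membrane genes then lost the call (camera adjusted p 0.332, 0.192 and 0.31), and cholesterol synthesis had 0.0411. Proliferation, NF-kB, mitochondrially encoded and immediate early genes gained one (0.00107, 0.0091, 0.0092 and 0.0223).

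When group labels were exchanged between libraries, 5 of 60 groupings, the real one included, called at least as many genes for the interaction as the real 18, and the highest other count was 6498. The 4 groupings with higher counts, 6498, 4830, 151 and 148, either exchanged all doxycycline labels within smoke or left those of smoke in place while moving air labels. They carry the effect of doxycycline into the interaction and point to that structure of the samples. The other 55 called at most 1 gene, among them 1 that exchanged all smoke labels and called 0. This count does not exclude chance for the interaction. For each of the other 4 comparisons the real grouping was the 1 of 10 with the highest count. The highest other counts were 1 for doxycycline in air and 0 for the other 3, and 10 groupings cannot reach a share under 0.1.

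The reporter sequences were in no comparison, and their levels are given because they were left unanalysed. EGFP had 208 ± 22.6, 236 ± 10.1, 248 ± 27.2 and 256 ± 7.33 CPM in air without doxycycline, air with it, smoke without it and smoke with it (SD, n = 3). tdTomato had 0.988 ± 1.6, 0.705 ± 0.186, 0.343 ± 0.176 and 2.03 ± 1.05 CPM. All 24 reporter counts were even numbers, against 50.1% of counts for 6985 genes with high counts in every library. How the reporter sequences were counted is not given, so their levels are not compared with those of genes.

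EPS8L1, PPP1R12C and RDH13 on chromosome 19 rose with doxycycline in both exposures, and 3 explanations were weighed. Reads shared with an overlapping gene would affect genes with shared exons, but 2 of these 3 share none. The spread in cell state would show as higher levels in replicate 2 than in replicate 3 of air without doxycycline, but the median log2 ratio was -0.483. Within 100 kb either side of PPP1R12C lay 3 of the 53 genes that rose over 2-fold in both exposures, against at most 2 in 19946 other windows. That window was chosen because these genes rose, so it does not test a doxycycline-switched insertion, which stays open because where the cassette sits is not given in the sources used here.

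Replicate 2 of air without doxycycline stood apart, and 3 explanations were weighed. A swap with a treated library is unlikely. Over 7 markers of doxycycline or smoke its highest level was 35.5% of the lowest treated library, with NPPC at 3.2% and HMOX1 at 2.44%. These markers were picked under the labels for no overlap between the groups compared, so a lower level was set by that choice. Only the size of the gap speaks against a swap, and a swap with a sample outside this set is not excluded. Depth is unlikely too, since thinning all libraries to its total of 42.8 M counts kept 96.9% of its gap. Within its group 17 of 18 alveolar type 2 markers were highest in this library. Independent genes would give 6, but these markers move together (estimated correlation 0.625), so that number is no fair comparison. The culture thus had higher type 2 markers, but whether this sets it apart on component 3 was not tested. Air libraries with doxycycline lay at 18.19 to 22 on that component, against -71.95 for this library.

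Part of the alveolar type 2 markers (4 of 18 in air, 7 in smoke) were higher and part of the transitional markers (7 of 15 in air, 11 in smoke) and of the matrix genes lower with doxycycline, and 3 explanations were weighed. Fewer contaminating fibroblasts are unlikely, since COL1A2 was at 0.0503% of COL1A1 in the libraries without doxycycline. A cell state that also varies among untreated cultures may contribute, since the log2 ratio of replicates 2 and 3 of air without doxycycline had a Pearson r of 0.749 with the doxycycline response in smoke across 11461 genes, with no library shared. An effect of doxycycline itself cannot be told apart from the knockdown without cells that carry a control guide. The median log2 fold change of 0.429 of the mitochondrially encoded mRNAs in smoke, with 1 of 13 called, decides nothing here.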

How the results depend on the processing

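Named genes gave 6798 values under the alternatives, of which 5660 kept direction and call, 1138 kept direction but lost the call and 0 reversed. The genes counted were called in the main fit, so they could lose a call but not gain one. Those of greatest change were also chosen for no overlap between the libraries compared, except for the interaction. The test against a 1.5-fold change reuses the main fold changes, and 295 of its values lost the call. The count of 0 reversed thus follows in part from these choices and does not measure robustness. Where a result below changed, the cause was not tested unless given.

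Against a 1.5-fold change, a stricter question by construction, 93, 280, 118, 243 and 0 genes were called for doxycycline in air, doxycycline in smoke, smoke without doxycycline, smoke with it and the interaction. Fits on only the libraries compared gave 275, 7161, 816 and 6226 for the first 4, and voom with library weights gave 5773, 7339, 6463, 6004 and 715. With 1 library left out the counts ran from 641 (air with doxycycline 1) to 5009 (air without 2), 2136 to 3500 (smoke without 1 and 2), 1212 (smoke without 3) to 4478 (air without 3), 1834 to 2716 (smoke with doxycycline 1 and 3) and 0 (air with doxycycline 2) to 660 (air without 3). Fewer libraries lower the power. The main fit estimates a single spread per gene over all 4 groups, but replicates of air without doxycycline lay further apart. Their counts differed by 57.3 to 193 times the sampling variance, against 12.9 to 35.4 in the other groups. The main fit can thus understate the spread for contrasts with air without doxycycline, and overstate it for those without that group. The interaction count was 5 with the 5 CPM filter, 3 with limma voom and 101 with DESeq2.

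ADGRG6 kept its fall with doxycycline in every alternative except the test against 1.5-fold (-0.70, adjusted p 0.84 in air and -0.81, adjusted p 0.164 in smoke). Its rise with smoke without doxycycline lost the call with library-size scaling (0.30), upper quartile scaling (0.33), against 1.5-fold (0.37) and with only the groups compared (0.37, adjusted p 0.116), and ran from 0.28 to 0.46 without air libraries 1 and 3. With doxycycline it gained a call with only the groups compared (0.25, adjusted p 0.016) and with library weights (0.27, adjusted p 0.0394).

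With an estimated correlation 0, 0, 1, 2 and 0 lists were called, and fry called 1 for the interaction. Across genes, r for smoke was 0.747 at a mean of at least 5 CPM and 0.741 among genes called in either contrast, and for doxycycline 0.796 and 0.797. Near ADGRG6 in smoke, 0 were called of the 3 genes left when up to 2 nearest tested genes were taken on each side.

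Replicates of the same number showed no pairing, as 0 of 18 same-numbered pairs had a correlation of deviations over 0.1 and 3 of 12 libraries correlated best with their own number. A block for that number gave 1442, 4406, 2097, 3172 and 1 called genes. Depth limited genes of low level, such as NPPC without doxycycline at 0.523 CPM.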

Other observations

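The groups in this part were put together after the data were seen. No test was made of them as groups. Of 9 tested EGF receptor ligands, AREG (1.82), EREG (1.24) and HBEGF (1.58) rose with smoke without doxycycline, and AREG (2.85), EREG (2.66), HBEGF (1.31), TGFA (1.42) and EGF (0.52) rose with it. Doxycycline in air lowered AREG (-1.61), EREG (-2.07), EPGN (-2.33) and NRG1 (-1.90). In smoke it lowered HBEGF (-1.34) and NRG1 (-1.91), while EGF (0.85) and BTC (0.59) rose.

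Smoke and doxycycline also changed single genes known from lung development. Of 10 lung progenitor transcription factors 6 fell without doxycycline, among them SOX9 (-1.51), SOX2 (-1.11) and MYCN (-1.17), and 4 fell and 1 rose with it, with SOX9 at -1.57, MYCN at -1.90 and FOXA1 at 0.34. With doxycycline 4 rose in air and 4 in smoke, FOXA2 by 0.54 and 0.70. Of 12 BMP ligands and targets 5 fell with smoke without doxycycline, BMP4 by -1.43 and ID2 by -0.89, and 7 fell with it, ID2 by -1.39, ID3 by -1.10 and BAMBI by -1.72. Doxycycline raised ID1 (0.66), ID2 (0.68) and ID4 (0.68) in air, and in smoke 2 rose and 4 fell, BMP4 by 0.99 and BMP7 by -1.06. Of 11 FGF and SHH pathway genes 6 fell and 1 rose with smoke without doxycycline, with SPRY1 at -1.42 and FGF9 at 1.53, and 6 fell and 2 rose with it. For doxycycline itself SPRY2 (0.45) rose and FGF20 (-0.68) fell in air, and 5 rose and 2 fell in smoke, SHH by -1.39. For the interaction edgeR called 0 genes in any of these 4 groups.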
